A study of Mus musculus with 4 samples.

How the data were processed

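Gene expression was measured with 4 single-colour microarrays, 1 per group. Mouse embryonic stem cells of 2 lines that carry a doxycycline-inducible c-Myc transgene (tetO:c-myc) were differentiated in vitro for 28 days, without doxycycline (dox) or in its presence. The line KY1.1 carries a Bmal1 promoter luciferase reporter, and the line called PER2Luc a PER2 luciferase reporter; both reporters read the circadian clock. The dox concentration was 40 ng/ml for KY1.1 and 500 ng/ml for PER2Luc, so line and concentration cannot be told apart in any difference between the lines' responses. The labels' design text states a single sample per cell type and treatment, so there are no replicates within a group.

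Per the labels' protocols, total RNA was amplified and coupled to Cy5, and per the file headers it was hybridised to a Toray mouse oligonucleotide chip and scanned. The deposited scanner files give, for each of 27456 spots, the median and mean spot intensity and the intensity of the surrounding area on the linear scanner scale; the header fields for normalization and background subtraction are empty, and 2736 BLANK spots averaged between 19.5 and 39.5 intensity units, so no background had been subtracted. The authors also deposited a value table. Its scale was read from the values, since no header or label records how it was made: each column followed the spot median minus the BLANK mean in a straight line (Pearson r from 0.999988 to 0.999993), had a median of 25.0 and left between 1620 and 2948 probes empty, most of which did not exceed the background level used here. The values are linear, uncentred intensities, and whether another step was applied is unknown. Above the median of its values the table deviated from that line by up to 19.3%.

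The 4 files and the reference tables used here do not pair the probe IDs of this chip with genes. The 43 gene lists planned for this work, which included Myc, the importins with Kpna2, and the core clock genes, could therefore not be placed on probes, none was tested, and no probe is named as a gene. The planned rule for named items takes the probes with the largest smaller-of-the-2 change in both lines, of which the first 2 higher and the first 2 lower are given by ID. The parts of that rule that need gene symbols were not applied, and the most extreme probes of a single line or in opposite directions are given as counts.

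Spot medians were background corrected with limma's normexp method (limma 3.58.1, R 4.3.3) and an offset of 50, quantile normalised over the 4 arrays and put on the log2 scale. The correction used the spot medians alone. The intensity around a spot followed the spot's own signal (correlation of log intensities between 0.774 and 0.936), so subtracting it may remove signal, which was not tested. The choice not to subtract it was made after the files were seen, and the fit with local subtraction is an added alternative. The offset pulls the folds of dim probes toward 0. Control spots were left out after background correction, 1 spot marked bad by the scanner software was removed with its probe, and 1 probe ID spotted more than once was averaged, which left 23472 probes. A probe counted as above background when its spot exceeded the mean of the BLANK spots of its array by more than 2 SD.

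Within a line, a probe was called higher or lower at a change of at least 2-fold with the brighter array above background; a pair of single arrays gives no p-value. Over both lines, limma's lmFit and eBayes (with a mean-variance trend) tested dox against no dox with line as a block, on probes above background on at least 2 of the 4 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. The no-dox and dox arrays of a line are paired by the cell line label. This fit has 1 residual degree of freedom per probe, which is the difference between the lines' responses. The eBayes step combines this spread with that of the other probes, with 2.86 prior degrees of freedom. Its p-values and standard errors (SE) thus reflect a probe's own spread between 2 lines only in part. Differences between the lines in their response could not be tested. The arrays of each line shared a scan date and detector gain (36 for KY1.1, 30 for PER2Luc). Each dox comparison thus lies within a scan date, while the line comparison is confounded with it. Depth in reads does not apply; the number of arrays limits the precision. The spot-to-spot SD of the 2 positive control sequences, each spotted 24 times, was between 0.105 and 0.192 on the log2 scale within an array.

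The joint fit was tested on simulated arrays of 20766 probes in which 200 probes changed in both lines, drawn 5 times per size with the spread between the lines that the real arrays show, reassigned at random over probes. At adjusted p under 0.05 it recovered a mean of 137.2 of 200 probes changed by 3 on the log2 scale, with 2 false calls, and 0 of those changed by 1 or by 2. At adjusted p under 0.1 it recovered 139.2 probes changed by 2, with 9.4 false calls, and 0 of those changed by 1. The 2-fold rule applied in both lines recovered 197.6 of the probes changed by 2, with 48.6 false calls, and 48.8 of those changed by 1, with 47.8 false calls. Each spread was taken from a single difference between the lines' folds of a probe, so the simulated spreads may be more uneven than the true ones. Every simulated probe counted as above background. Reassigning the spread removes any link between spread and brightness, and only 200 probes changed, so these rates may not hold for the real arrays. There the fit called 0 probes at 0.05, although the mean log2 fold of 1 probe was -6.27. The 0 calls therefore do not show that large changes are absent.

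The gene lists, the rule for named items, the 2-fold rule, the joint test and a first set of alternatives were chosen before the data were examined. Those alternatives were median scaling, cyclic loess, background subtraction without an offset, no background correction, other filters on dim probes, the authors' value table, a 1.5-fold or 3-fold rule, no line block, no trend, and leaving out each array. Averaging the probes of a gene and all alternatives on gene lists were not run, for want of gene names. Local background subtraction, normexp without an offset, a background level from spots without a probe, spot means, control spots kept in the quantile step, an adjusted p of 0.1 and an exchange of the dox labels of PER2Luc were added after the data were seen. An early run with the control spots kept was the first made; they were then left out, as is usual for control spots, and the closing section gives both results. Figures were drawn with matplotlib 3.10.9.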

Results

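The data were 4 whole-transcriptome arrays of embryonic stem cells differentiated for 28 days, from the lines KY1.1 and PER2Luc, each without dox and with dox, the inducer of a transgene for c-Myc, a transcription factor of growth and proliferation. The study's title asks how Kpna2, an importin, shapes the circadian clock that develops as cells differentiate. The dox comparison sets cells differentiated with the inducer of the c-Myc transgene against cells differentiated without it; the level of c-Myc itself was not analysed here. Of 23472 probes, 20859 (88.9%) lay above background on the KY1.1 array without dox and 19780 (84.3%) on the KY1.1 array with dox. The corresponding numbers for PER2Luc were 20273 (86.4%) and 19752 (84.2%). These counts use the level from BLANK spots. With a level from spots without a probe, 19601 probes passed without dox and 17341 with dox in KY1.1. In PER2Luc these were 19531 and 17457. On the KY1.1 array with dox, 44.7% of the spots without a probe passed the BLANK level, so passing it there is weak evidence of expression. The brightest probe of each array read between 49141 and 52369 intensity units, below the scanner limit. Probes carry no gene names here, so Myc, Kpna2 and the clock genes were not analysed.

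In KY1.1, 354 of 21181 evaluated probes were at least 2-fold higher with 40 ng/ml dox and 650 were at least 2-fold lower, together 4.74% of the probes. Among the larger differences most were lower: 230 probes were at least 3-fold lower and 43 at least 3-fold higher, and at a log2 difference of 3 or more 36 were lower and 2 higher. The median log2 fold was 0.031 and the SD over probes 0.48. The called higher probes had a median log2 fold of 1.19 and the called lower probes of -1.39. For 42 of the 650 lower probes the dox array was not above background, so their difference is a lower bound. With 1 array per group these differences have no replicate check, and the counts depend on the offset of the background correction: the same correction with no offset gave 1191 higher and 1814 lower probes.

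PER2Luc cells, which received 500 ng/ml dox, showed 721 of 21062 probes at least 2-fold higher and 847 at least 2-fold lower, 7.44% of the probes. At 3-fold, 159 were higher and 333 lower, and at a log2 difference of 3 or more 16 were higher and 60 lower. The dimmer array was not above background for 5 of the 721 higher and 37 of the 847 lower probes, so their difference is a lower bound. The SD of the log2 fold over probes was 0.59, which is 1.22 times that of KY1.1. Higher probes made up 46.0% of the calls against 35.3% in KY1.1; in PER2Luc they were the majority under median scaling (52.0%) and in the authors' value table (55.1%), and with local background subtracted the order of the lines turned (44.9% in PER2Luc, 47.6% in KY1.1). Median scaling moved the median log2 fold of probes above background on any array to 0.19 in KY1.1 and 0.13 in PER2Luc, so the level of the folds depends on the scaling. Whether the responses of the lines differ in size was not tested, since neither line has a replicate, and without the offset 1918 probes were higher and 2233 lower.

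**Figure D1:**
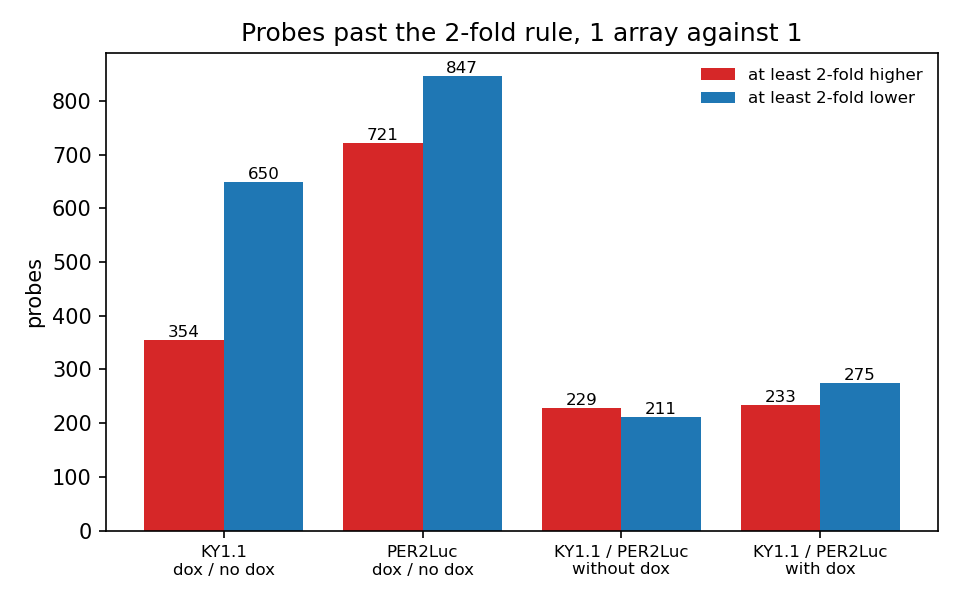
Bars give the number of probes (y axis) at least 2-fold higher (red) or lower (blue) in 4 comparisons of a single array with another (x axis), with the count above each bar. The dox comparisons hold 1004 calls in KY1.1 and 1568 in PER2Luc, more than the 440 between the lines without dox.

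Most calls shared by the lines had the same direction. Among 20391 probes evaluated in both, 232 were at least 2-fold higher in both lines and 400 at least 2-fold lower in both, where independent lists of these sizes would share 12.5 and 27.0. For 33 of the 400 a dox array was not above background. Without the offset the shared calls were 671 and 1062, the authors' value table gave 746 and 1213, and local background subtraction kept 118 of the 232 and 246 of the 400. Of the KY1.1 calls, 65.5% of the higher and 61.6% of the lower probes were also called in PER2Luc, and 32.3% and 47.2% of the PER2Luc calls were also called in KY1.1. Fisher's exact test gave odds ratios of 76.3 (95% confidence interval 60.1 to 97.6) for higher and 69.2 (57.5 to 83.6) for lower probes; it counts probes, which are not independent replicates. In the opposite direction, 25 probes were lower in KY1.1 and higher in PER2Luc, where independence gives 22.9, and 1 was higher in KY1.1 and lower in PER2Luc, where it gives 14.7. These counts depend on the background correction: they were 73 and 13 without the offset, 159 and 86 with plain subtraction, 115 and 10 in the authors' value table, and 23 and 28 with local background subtracted. The numbers expected under independence and the odds ratios assume the same rate of calls at every brightness. In KY1.1, 8 of 2119 probes were lower in the dimmest of 10 brightness classes and 254 of 2118 in the brightest. In PER2Luc these were 0 and 280 of 2107. Expected numbers that allow for brightness were not computed, so those given may be too low and the odds ratios too high. Whether the 25 probes exceed their expected number therefore cannot be told.

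The probes called in KY1.1 had medians of similar size in PER2Luc. The PER2Luc arrays entered the choice of these probes through the shared quantile normalization and the limit to probes evaluated in both lines. The 354 higher probes had a median log2 fold of 1.25 in PER2Luc, with 342 (96.6%) above 0, and the 649 lower probes had a median of -1.25, with 593 (91.4%) below 0. For the probes called in PER2Luc, the medians in KY1.1 were 0.82 for 718 higher and -0.95 for 847 lower probes, against 1.27 and -1.41 in PER2Luc itself. Across the 20391 probes the lines' log2 folds correlated with Pearson's r = 0.71 and Spearman's rho = 0.67, a correlation across probes, which are not independent replicates; with local background subtracted r was 0.476 and rho 0.433. The SD of the difference between the lines' folds was 0.42, and 554 probes differed by at least 2-fold between the lines in their fold.

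Probe M200000925 had the largest positive fold shared by the lines. Its log2 intensity went from 8.03 to 12.78 in KY1.1, 26.9-fold higher with dox, and from 6.98 to 12.84 in PER2Luc, 58.1-fold higher; over the alternatives its log2 fold ran from 4.33 to 5.36 in KY1.1 and from 5.77 to 7.06 in PER2Luc. M400010878 followed, 6.45-fold higher in KY1.1 and 11.4-fold higher in PER2Luc. The largest shared negative fold was that of M200003295, which was among the brightest probes without dox, with raw spot medians of 31107 in KY1.1 and 41210 in PER2Luc. With dox its spot medians were 302 and 594, which is 82.5-fold lower in KY1.1 and 71.7-fold lower in PER2Luc after normalization. M200000404 was 25.1-fold lower in KY1.1 and 74.0-fold lower in PER2Luc, and its spots with dox, at 49 and 28 intensity units, lay just above the background levels of 42.0 and 22.8; over the alternatives its log2 fold ran from -7.00 to -3.33 in KY1.1 and from -8.96 to -5.01 in PER2Luc. All 4 probes had the same direction in both lines because the rule that picked them requires it.

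**Figure D2:**
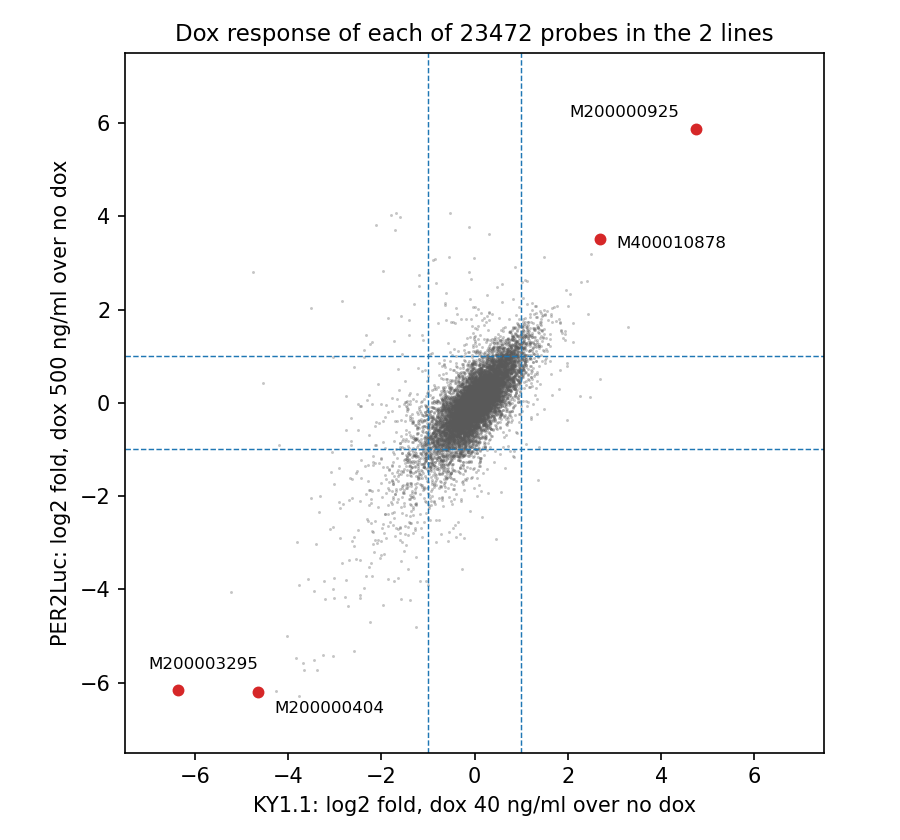
Each grey point is a probe, with its log2 fold (dox over no dox) in KY1.1 on the x axis and in PER2Luc on the y axis; dashed lines mark 2-fold, and red points are the 4 probes given by ID. All 23472 probes are drawn; among the 20391 evaluated in both lines r is 0.71, with 400 probes beyond 2-fold in the lower left and 232 in the upper right corner.

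In the joint limma fit of 20766 probes, 0 passed an adjusted p of 0.05. The lowest adjusted p was 0.054, for M200003295 (mean log2 fold -6.27 ± 0.15, moderated SE, n = 2 lines, limma). M200000925 (5.31 ± 0.32), M400010878 (3.10 ± 0.26) and M200000404 (-5.43 ± 0.42) each had an adjusted p of 0.071 in limma. All 4 passed 0.05 under median scaling (adjusted p from 3.97e-05 to 0.00227), in the authors' value table (0.0106 to 0.0216) and with spot means (0.0274 to 0.0457), and with local background subtracted each had an adjusted p of 0.241 in limma. At an unadjusted p under 0.05 the fit gave 5641 probes, 27.2% of those tested, of which 2899 were higher and 2742 lower. At an adjusted p under 0.1 in limma, a level chosen after the data were seen, 1224 probes were higher and 1270 lower. Among them were 230 of the 232 probes called higher and 392 of the 400 called lower in both lines by size. Both rules use the same folds on the same arrays, so this overlap is no separate support. At the level of 0.1 the total was 0 with local background subtracted and 670 without the line block. The count at 0.05 depends on the scaling, with 4289 probes under median scaling. With spot means in place of medians it was 264, and the authors' value table, which differs in scaling, background and the probes listed, gave 1915.

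Without dox, KY1.1 and PER2Luc cells differed less from each other than either did from its dox-treated counterpart. Of 21370 probes, 229 were at least 2-fold higher in KY1.1 and 211 at least 2-fold lower, 2.06% of the probes, with an SD of the log2 difference of 0.35. Lower probes were the majority under median scaling (180 and 325), cyclic loess (210 and 252), local background subtraction (543 and 596) and in the authors' value table (1183 and 1281), and without the offset the counts were 963 and 868. With local background subtracted, the dox comparison in KY1.1 gave 603 higher and 663 lower probes, close to the 543 and 596 between the lines. With dox, 233 of 20739 probes were higher in KY1.1 and 275 lower, with an SD of 0.38. Over the 18352 probes above background on all 4 arrays, the arrays without dox correlated at r = 0.975 and those with dox at r = 0.969, while dox and no-dox arrays correlated at 0.952 within KY1.1 and 0.929 within PER2Luc. Of 427 probes that differed between the lines without dox, 107 (25.1%) differed in the same direction with dox, where independence gives 5.30. That expected number also assumes the same rate of calls at every brightness, so it may be too low. Line, scan date and detector gain coincide in the comparison of the lines, so they cannot be told apart.

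**Figure D3:**
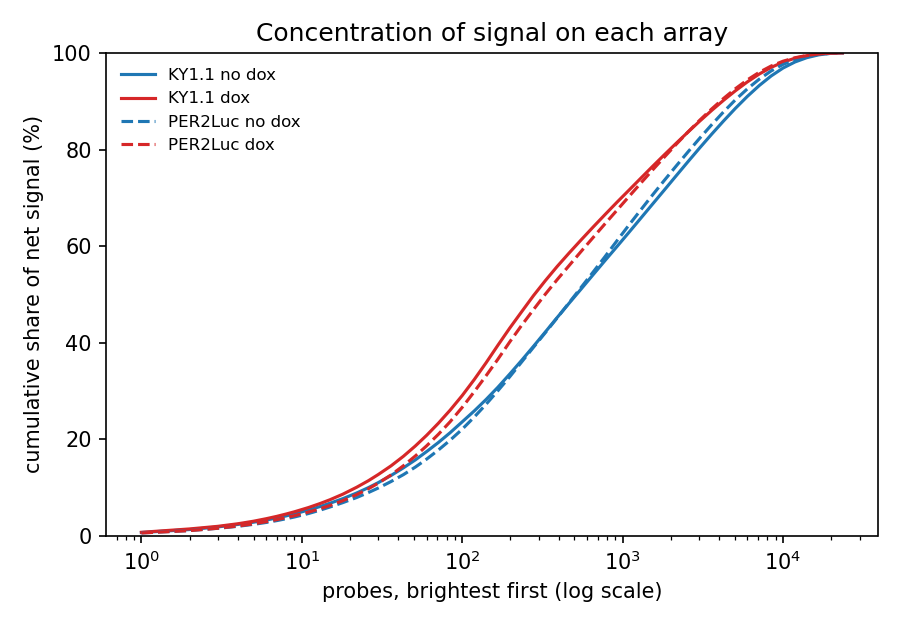
Lines give the cumulative share of background-subtracted signal (y axis, %) held by the brightest probes of each array (x axis, number of probes, log scale), red with dox and blue without, solid for KY1.1 and dashed for PER2Luc. At 100 probes the dox arrays reach 29.0% and 26.6% and the no-dox arrays 23.6% and 22.1%.

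The signal was held by fewer probes on the dox arrays. The 100 brightest probes took 23.6% of the background-subtracted signal in KY1.1 without dox and 29.0% with dox, and 22.1% and 26.6% in PER2Luc. The 1000 brightest took 61.3% and 70.3% in KY1.1 and 62.6% and 68.8% in PER2Luc. Of the 100 brightest probes, 78 were the same with and without dox in each line. Quantile normalization gives all arrays the same distribution, so the quantile-normalised folds above do not show this difference. Removing it can itself shift folds by brightness, which was not tested. Folds under median scaling keep the difference.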

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

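The tests of detector gain and of the amount of labelled RNA in this part were chosen after their values could be seen; the others were set down before their values were computed. The lines pointed in opposite directions for some probes at the 2-fold rule: 25 were lower in KY1.1 and higher in PER2Luc, and 1 was higher in KY1.1 and lower in PER2Luc. With local background subtracted these counts were 23 and 28, so the excess of the former depends on the background correction. This difference between the lines was not tested, since each line has a single pair of arrays. Among spots outside the main measurement, the 24 spots of positive control 3 were higher with dox after median scaling, by 1.01 on the log2 scale in KY1.1 and 0.86 in PER2Luc, with standard errors over spots of 0.033 and 0.042, while the log2 differences of positive control 2 were -0.13 and -0.21. Spots labelled as holding no probe exceeded the background level in 44.7% of 1102 cases on the KY1.1 array with dox, against 22.6% without dox, and in 11.6% and 10.5% on the PER2Luc arrays.

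The log2 folds of the lines ran together across probes (r = 0.71). A fold that depends on brightness alike in both lines is argued against by the correlation within 20 brightness classes. Its median was 0.613, against a bound of 0.5 set beforehand. In classes 1 to 7, counted from the dimmest, the correlation lay below 0.5 (0.246 to 0.473). For these dimmer probes the argument is weak. A fold that depends on the place on the chip, which all arrays share, is argued against by the correlation after subtracting the median of neighbouring probes, which was 0.725. Dox acting on the cells without the c-Myc transgene stays open and may account for any part of the shared response, since 0 arrays hold dox-treated cells without the transgene. A response to c-Myc, which the design names, also stays open and untested.

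The 100 brightest probes took a larger share of the signal on the dox array of both lines, by 5.44 percentage points in KY1.1 and 4.52 in PER2Luc. Scanner gain cannot account for it, since the largest gain difference within a line was 0. The level subtracted as background is argued against because the smaller of the lines' increases was 4.37 points with no subtraction at all. The amount of labelled RNA stays open: total signal with dox was 94.5% of that without in KY1.1 and 106.2% in PER2Luc, and with 1 array per group the product of these log2 ratios (-0.00705) has no spread to be judged by, while the raw positive controls moved apart with dox in both lines (control 2 from 5191 to 3099 and 6997 to 4872, control 3 from 16112 to 21037 and 19127 to 27792). A different makeup of the RNA with dox may also account for it and was not tested.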

How the results depend on the processing

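Chosen after the data were seen were local background subtraction, normexp without an offset, the background level from spots without a probe, spot means, control spots kept in the quantile step, the adjusted p of 0.1, the exchanged labels and all tests on median scaling. Both correlations stayed positive. The balance of calls turned in PER2Luc, to 923 higher and 853 lower under median scaling and 2700 and 2204 in the authors' table, and between the lines without dox, from 229 and 211 to 210 and 252 under cyclic loess and 180 and 325 under median scaling. A 1.5-fold rule gave 1446 higher and 1561 lower probes in KY1.1, 1955 and 1964 in PER2Luc, 1003 and 1011 in both, and 770 and 764 between the lines without dox; a 3-fold rule gave 43 and 230, 159 and 333, 21 and 135, and 68 and 52. The authors' value table gave 1093 and 2335 in KY1.1, 2700 and 2204 in PER2Luc, 746 and 1213 in both, and 1183 and 1281 between the lines; normexp without an offset gave 1191 and 1814, 1918 and 2233, 671 and 1062, and 963 and 868; plain subtraction without an offset gave 1961 and 2557, 2802 and 3065, 940 and 1397, and 1776 and 1624, with a correlation between the lines of r = 0.602. Local background subtraction gave 603 higher probes in KY1.1, 543 higher and 596 lower between the lines, r = 0.476, rho = 0.433 and a share of higher calls of 47.6% in KY1.1 and 44.9% in PER2Luc, which turns the order of the lines. Without background correction 360 probes were higher in KY1.1 than in PER2Luc without dox, and under median scaling 325 were lower. Of the 232 higher and 400 lower probes called in both lines, local subtraction kept 118 and 246, cyclic loess 169 and 388, and median scaling 182 and 354.

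The joint test at an adjusted p of 0.05 gave 0 probes in the reported fit, 4289 under median scaling, 1915 in the authors' value table, 264 with spot means, 16 with normexp without an offset, and 1 each under cyclic loess, with control spots kept in the quantile step (lowest adjusted p 0.0405, from limma), with probes above background on all 4 arrays and with the background level from spots without a probe. At 0.1 the reported 2494 became 8367 under median scaling, 3878 in the authors' table, 670 without the line block, 0 with local background subtraction and 0 with the labels of PER2Luc exchanged, which swaps the mean and the residual of the lines' folds and so restates their correlation. M200003295 also passed 0.05 under cyclic loess, on probes above background on all 4 arrays, with the level from spots without a probe, without the offset and with control spots kept (adjusted p from 0.0277 to 0.0422, limma). Leaving out each array in turn was possible only without the block and gave between 0 and 0 probes at both levels; with the block it leaves no residual degrees of freedom. The lowest adjusted p over the alternatives with the labels as given ran from 3.97e-05 to 0.375. Apart from median scaling and the offset, the cause was not tested.

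The log2 folds of the 4 probes given by ID kept their sign under all 12 alternatives. Those that change only which probes count as above background leave the folds as they are, so they could not change a sign. Those of M200003295 ran from -7.00 to -6.28 in KY1.1 and from -6.30 to -5.80 in PER2Luc, and those of M400010878 from 2.51 to 3.07 and from 3.33 to 4.05. Alternatives on gene lists and on the probes of a gene were not run, because no probe could be tied to a gene. The offset of 50 limits the size of folds over much of the chip, not only for the dimmest probes. Without and with dox, the median probe spot read 80 and 64 intensity units in KY1.1, and 57 and 48 in PER2Luc. The BLANK means were 39.0, 39.5, 19.5 and 19.5, so less than the offset remained above them.

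Median scaling called many more probes in the joint fit than quantile normalization. A larger number of prior degrees of freedom in the variance model could account for this: it was 6.64 under median scaling and 2.86 under quantile normalization, and the median-scaled statistics read with the latter called 0 probes. The offset, scaled with the array, may add to the dim probes that were higher with dox, since BLANK spots were higher by 0.327 in KY1.1 and 0.204 in PER2Luc; it is argued against for the 33.2% of called probes (1425) that were lower. Dim probes higher with dox in both lines stay open: in the authors' value table the median log2 fold of the dimmer probes was -0.157 in KY1.1 and 0.11 in PER2Luc, but its columns are each scaled to the same median, so this decides nothing.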

Other observations

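The splits by brightness in this part were chosen after the results were seen, and no explanation of them was tested. Probes were put into 10 classes by their brightness on the no-dox array of the other line, so that chance extremes of a line's own array do not set its classes. In the brightest class 254 of 2118 probes were lower with dox in KY1.1 and 60 higher; in PER2Luc 280 of 2107 were lower and 113 higher. In KY1.1 lower probes outnumbered higher ones in every class except classes 6 (32 lower and 33 higher) and 7 (66 and 75), counted from the dimmest. The margins were widest in classes 9 (152 and 81) and 10, and small in classes 1 (8 and 1) to 5 (22 and 18). A probe of a dim class on the PER2Luc array can be bright in KY1.1. Whether the excess in KY1.1 reaches dim probes therefore cannot be told. In PER2Luc lower probes outnumbered higher ones in classes 9 (199 and 133) and 10 only. The offset compresses the folds of dim probes in both directions, and quantile normalization fixes the top of the distribution, which leaves bright probes less room to be higher, so the rates of calls cannot be compared between classes.

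Of the 100 brightest probes without dox, 83 were shared by the lines. With dox the lines shared 87 of their 100 brightest probes.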
